A study of Mus musculus with 10 samples.

How the data were processed

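Small RNA was sequenced from 10 livers of 14-week-old mice, 5 from littermate controls and 5 from mice with a liver knockout of Tsc1, per the labels. Total RNA had been extracted with TRIzol and sequenced on an Illumina instrument, per the labels' protocols. The deposited table holds 1 column per library and 285 mature miRNAs under older miRBase-style names, so some names carry no arm. All 10 columns were matched to samples by the library number in their names, which the sample descriptions also give. Group and replicate number in the names fit that match. The library numbers were consecutive within each genotype, so an effect of any order that followed them could not be told apart from genotype.

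The deposited values are a normalised signal in which the authors scaled miRNA read counts by 1 factor per library. The submitters' processing notes name DESeq, without a version. The aligner, the miRNA annotation, the genome build and any filter on miRNAs are not given in the sources used here. Every value of a library was a whole multiple of 1 step within 0.001, in 100% of values, and that step is what 1 read is worth. It lay between 0.711 and 1.68 normalised reads. Division by the step gave between 6228497 and 12129069 miRNA reads per library, which is the depth over the listed miRNAs. The table was kept as normalised values for the main test, and the whole reads entered 1 alternative. Reads counted without molecular identifiers are not independent molecules, and binomial intervals and read floors given here cover counting error only.

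Values were compared as log2(normalised value + 1) with limma 3.58.1 in R 4.3.3, using a linear model of genotype with empirical Bayes moderation and an intensity trend. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of miRNAs with few reads. A mean of at least 5 normalised reads over the 10 libraries was required, and all 285 miRNAs met it. Single values per library were compared with 2-sided exact permutation tests over all 252 splits of the libraries into 5 and 5, for which the smallest possible p is 0.00794. The fit was tested on simulated libraries of 285 miRNAs, of which 60 were changed in each of 20 runs, equally up and down. Counting noise at the observed depth was added to the observed spread. That spread already holds such noise, so miRNAs with few reads varied more than in the data. The fit recovered 56.3% of changes of 2-fold and 92.3% of changes of 4-fold in this comparison, and 3.62% of its calls were false. Errors were drawn independently for each miRNA, whereas miRNAs of the real libraries deviated together and most called ones rose. These rates may therefore not hold for the real data.

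Before the data were examined, 18 lists of miRNAs were fixed, covering the Dlk1-Dio3 locus and 2 parts of it, other imprinted clusters, cell types of liver and neighbouring tissues, let-7, miR-17-92 and its paralogs, liver injury, and glucose and lipid metabolism. The series names the Dlk1-Dio3 locus in its title, after these libraries were seen by its authors, so that list is not independent evidence of a direction. Lists of at least 3 tested members were compared with the other miRNAs by camera with a preset correlation of 0.01 and again with an estimated correlation, and tested for a common direction with fry. The calibration of these tests was checked on 99 other splits of values from which the genotype means had been removed.

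The text names, by a rule fixed beforehand, the 12 miRNAs with the highest and the 12 with the lowest fold change among those past the threshold with a mean of at least 20 normalised reads, the 8 most abundant miRNAs, the 5 most abundant and 5 most changed locus members, and the most abundant member of each other list. Where fewer than 5 passed in a direction under that rule, the 5 with the smallest p were taken. Other called miRNAs are named where a count is small, chosen after their values were seen. Hairpin positions were taken by name from the GENCODE M21 annotation of GRCm38, in which 274 of the 285 miRNAs, or 96.1%, had a hairpin gene. Closely related miRNAs, such as let-7 members or miR-199a and miR-199b, may share reads, and their values are uncertain to that extent.

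The alternatives tried were other pseudocounts and filters, 4 other scalings, limma without the trend or with array weights, a replicate block, and each library left out in turn. After the data were seen, voom on whole reads, removal of a slope on hairpin GC content, and 2 sets of left-out libraries were added. Figures were drawn with matplotlib 3.10.9.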

Results

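The series measured mature miRNAs in mouse liver to ask how loss of Tsc1, a subunit of the TSC complex that restrains mTORC1 signalling, alters miRNA expression. It compared 5 control livers with 5 Tsc1 mutant livers at 14 weeks of age. The libraries held 10109114 ± 2418319 miRNA reads in controls and 9181816 ± 1759628 in mutants (SD, n = 5 each), a difference within the spread between libraries (exact permutation p = 0.484). Tsc1 messenger RNA was not analysed here, so the genotype labels were not checked against the targeted gene. No 2 libraries held identical values, and 0 of 45 pairs agreed within sampling noise by a chi-square test.

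Both genotypes were dominated by the hepatocyte miRNA miR-122. It made up 32.9 ± 5.30% of normalised reads in controls and 29.3 ± 4.52% in mutants (SD, n = 5 each). Its log2 fold change was -0.21 ± 0.19 (SE), with a limma adjusted p of 0.608. The other most abundant miRNAs also stayed short of the threshold. Their log2 fold changes were -0.12 for miR-21, -0.01 for miR-192, 0.06 for miR-148a, 0.10 for miR-30a, 0.31 for let-7f, 0.41 for let-7g and 0.40 for miR-101b. Of these, let-7g had the smallest limma adjusted p, 0.0867, and it passed under some other settings.

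The miRNAs of the Dlk1-Dio3 locus were higher in Tsc1 mutant liver. This imprinted domain on chromosome 12 expresses its miRNAs from the maternal allele. Of 31 listed members in the table, 28 rose and 0 fell, with a median log2 fold change of 2.56, a 5.89-fold difference. The median of the 254 other miRNAs was -0.09. In 26 of the 31 members every mutant library lay above every control library, an order that chance gives in 0.397% of splits for 1 miRNA. With p-values adjusted over the list alone, 31 members passed, which is not independent evidence because the study named the locus from these libraries.

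The most abundant members carried the same difference. Expression of miR-127, whose hairpin lies antisense to an exon of Rtl1 at 109592846 to 109592915 on chromosome 12 (GRCm38), was 1340 ± 427 normalised reads in controls and 8126 ± 1748 in mutants (SD, n = 5 each). Its log2 fold change was 2.62 ± 0.23 (SE), with a limma adjusted p of 1.37e-05. The next by abundance were miR-541 at 2.55, miR-379 at 2.75, miR-381 at 2.85 and miR-411 at 2.76 on the log2 scale. The highest fold change was that of miR-376b, at 3.13 ± 0.28 (SE), which rose from 53.5 ± 20.9 to 458 ± 95.2 normalised reads (SD, n = 5 each). Other members with a high fold change were miR-665 at 3.00, miR-377 at 2.90, miR-299 at 2.88, miR-136 at 2.84, miR-341 at 2.83, miR-434-5p at 2.78, miR-409-5p at 2.77 and miR-337-5p at 2.62. In controls miR-377 had a mean of only 2.69 normalised reads, close to the 2.13 to 5.05 that 3 reads were worth. The 3 members that missed the threshold were miR-495 at 1.31, miR-323-3p at 1.28 and miR-543 at 2.41.

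**Figure D1:**
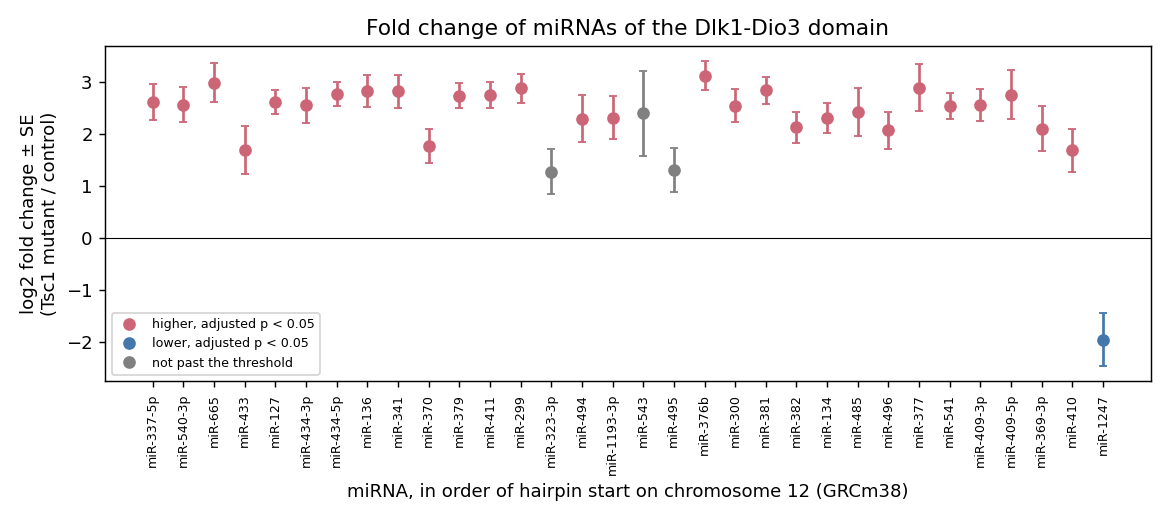
Log2 fold change between Tsc1 mutant and control liver (limma, 5 libraries per group, bars are SE) of miRNAs of the Dlk1-Dio3 domain, in order of hairpin start on chromosome 12 (evenly spaced, not to scale). The 31 listed members lie between 1.28 and 3.13, and miR-1247 at the Dio3 end, on the opposite strand, lies at -1.95.

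Both annotated parts of the locus took part. In the part antisense to Rtl1, all 5 members rose, and in the part from miR-379 to miR-410, 18 of 21 did. In GRCm38 the annotation places Meg3 at 109541001 to 109571726, Rian at 109603940 to 109661716 and Mirg at 109729764 to 109749460 on chromosome 12. Hairpins of miR-341 and miR-370 lie in introns of Rian, and those of miR-377 and miR-410 in exons of Mirg.

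Summed over its members, the locus gave 3895 ± 1341 normalised reads in controls and 23497 ± 4455 in mutants (SD, n = 5 each). The difference was 2.63 ± 0.25 on the log2 scale (SE), or 6.19-fold, with a 2-sided exact permutation p of 0.00794, the smallest this design allows. As a share of miRNA reads the locus rose from 0.0413 ± 0.0164% to 0.255 ± 0.0492% (SD, n = 5 each). The lowest mutant share was 0.169% (95% exact binomial interval 0.166 to 0.171%) in replicate 5, and the highest control share was 0.0694% (0.0679 to 0.0709%) in replicate 2. Control replicate 2 also had high epithelial and muscle miRNAs. Without it the log2 difference of the sum was 2.80.

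**Figure D2:**
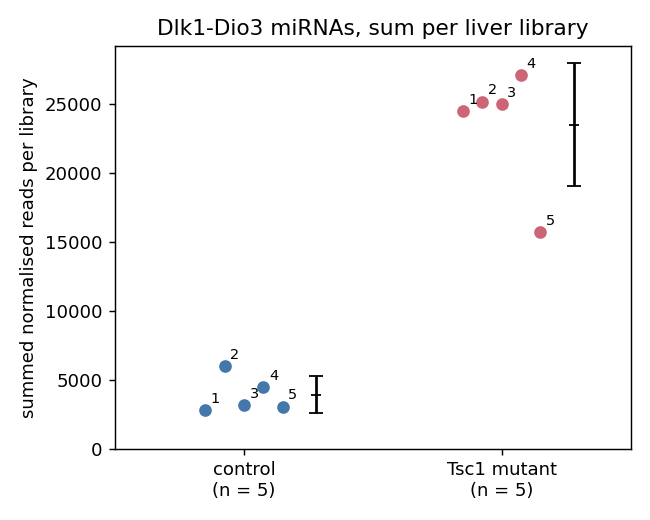
Summed normalised reads of the 31 Dlk1-Dio3 miRNAs in each liver library (points, numbered by replicate), with the group mean and SD as bars. The 5 mutant libraries lie between 15723 and 27083, above the 5 control libraries at 2774 to 5982.

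Compared with the other miRNAs, the locus list was higher in mutants by camera with a preset correlation (p = 1.05e-48). The size of that p cannot be read as usual, because its members varied together, with an estimated correlation of 0.528. With the genotype means removed, the preset test still gave p below 0.05 in 61 of 99 splits. With an estimated correlation the list kept its call (p = 0.000819, adjusted p = 0.0115), and that test gave p below 0.05 in 6 of the 99 splits. The fry test of a common direction in limma gave p = 1.17e-05, and p below 0.05 in 4 of these permutation splits. Of the 2 parts, the one from miR-379 to miR-410 had a camera adjusted p of 0.0429 with an estimated correlation. The part antisense to Rtl1 had a camera adjusted p of 0.0913 with an estimated correlation, so its camera call was lost. Each part was compared with miRNAs that include the rest of the raised locus, which works against both. By fry the adjusted p was 8.18e-05 for the part antisense to Rtl1 and 0.000123 for the other. Calibration was not checked for the parts.

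Across all 285 miRNAs, 31 rose and 6 fell in Tsc1 mutant liver. The 3 that rose outside the locus were miR-802, miR-29a and miR-137. P-values were adjusted over all miRNAs together, so the many locus calls ease the Benjamini-Hochberg cutoff for miRNAs outside the locus. Calls outside it with a larger p, such as those of miR-29a and miR-137, lean on this, and so may most of the miRNAs that fell. Expression of miR-802 was 495 ± 165 normalised reads in controls and 1583 ± 285 in mutants (SD, n = 5 each). It was higher in 5 of 5 mutants than in any control, with a log2 fold change of 1.72 ± 0.24 (SE) and a limma adjusted p of 0.000258. The log2 fold changes of miR-29a and miR-137 were 0.34 and 0.90, both with a limma adjusted p of 0.0395, and both calls were lost when single libraries were left out. With a slope on hairpin GC content removed, miR-29a was at 0.053 (limma adjusted p = 0.843).

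**Figure D3:**
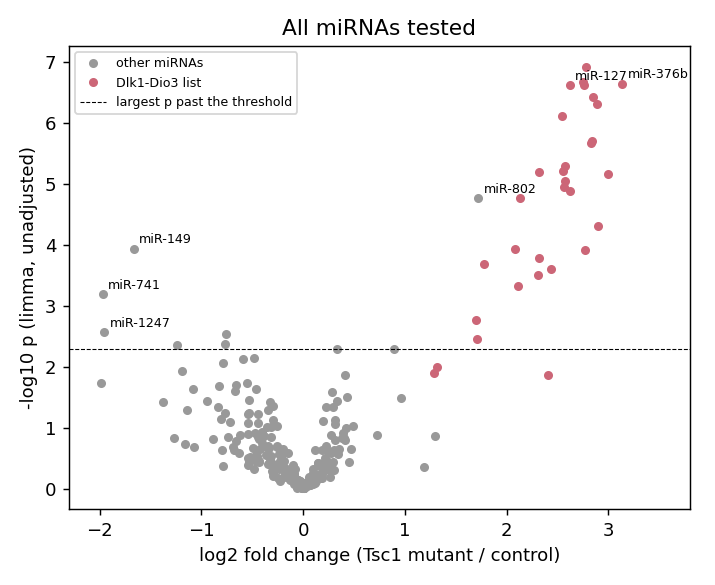
Log2 fold change (Tsc1 mutant over control) against -log10 of the unadjusted limma p for the 285 miRNAs, 5 libraries per group. Red points are the 31 Dlk1-Dio3 miRNAs, which lie at the right, and the dashed line marks the largest p past the adjusted threshold.

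The 6 miRNAs that fell were miR-149, miR-741, miR-1247, miR-582-3p, miR-320 and miR-3962. None is in the locus list, so all were called at the cutoff eased by the locus calls. Adjustment over the miRNAs outside the locus alone was not run. The unadjusted limma p was 0.000115 for miR-149 and 0.000639 for miR-741. Among the others it ran from 0.00272 for miR-1247 to 0.00437 for miR-582-3p. Calls other than that of miR-149 may therefore not hold under such an adjustment. Expression of miR-149 was 384 ± 195 normalised reads in controls and 112 ± 16.6 in mutants (SD, n = 5 each), a log2 fold change of -1.67 ± 0.29 (SE) with a limma adjusted p of 0.00149. The log2 fold changes of the others were -1.97 for miR-741, -1.95 for miR-1247, -1.24 for miR-582-3p, -0.77 for miR-320 and -0.76 for miR-3962. In mutants miR-741 and miR-1247 had means of 4.46 and 2.42 normalised reads, which is a few reads per library. Calls were lost in 10 of 25 other settings for miR-320, which was at -0.44 (limma adjusted p = 0.248) with the GC slope removed, in 9 of 24 for miR-582-3p, in 7 of 24 for miR-1247 and in 4 of 25 for miR-3962. The number that fell was sensitive to the model, at 23 with array weights, and to single libraries. It was 10 without control replicate 1, 3 without control replicate 3, 3 without control replicate 5 and 2 without Tsc1 mutant replicate 4.

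Among the lists of liver cell types, 1 of 5 hepatocyte miRNAs rose, which was miR-802, and no member of the other cell type lists passed the threshold. The median log2 fold change was -0.01 for hepatocyte, 0.11 for 3 erythroid, -0.23 for 8 leukocyte, -0.08 for 6 stellate and smooth muscle and -0.05 for 2 endothelial miRNAs. Their most abundant members were at 0.11 for miR-486, -0.21 for miR-146a, -0.39 for miR-143 and -0.02 for miR-126-3p. The 5 biliary epithelial miRNAs had a median of -0.74 and the 3 striated muscle miRNAs one of -1.27, with miR-200b at -0.68 and miR-1a at -1.27. Both lists were raised in control replicate 2. Of the striated muscle list, miR-133a was at -1.99 (limma adjusted p = 0.110), and at -1.31 without control replicate 2. It passed as lower with array weights. The 2 neural miRNAs had a median of -0.47, with miR-219-5p at -0.28, and 1 of them, miR-9, passed when adjusted over the list alone. Over all miRNAs, miR-9 passed as lower with the GC slope removed. The exocrine pancreas list had 0 members in the table.

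The let-7 family of 9 miRNAs had a median log2 fold change of 0.01, and the 11 miRNAs of miR-17-92 and its paralogs one of 0.02, with miR-92a at -0.47. The 8 liver injury and tumour miRNAs had a median of -0.28. The 4 miRNAs of other imprinted loci had a median of -0.24, with miR-335-5p at -0.13, and miR-669c of the Sfmbt2 cluster was at -0.44. No member of these lists passed the threshold. Without control replicate 1, miR-92a passed as lower at -0.73 (limma adjusted p = 0.0210). Of the liver injury list, miR-222 passed there as lower and miR-34a as higher. These 3 also passed, in the same directions, with array weights and in both settings without the replicates 1. Of the other imprinted loci, miR-296-3p was at -1.08 with all libraries (limma adjusted p = 0.129). It passed as lower without control replicate 4, with array weights and with the replicate block. Of 12 miRNAs linked to glucose and lipid metabolism, 1 rose, which was miR-29a, and 0 did when adjusted over the list alone. Its most abundant member, miR-378, was at 0.44 with a limma adjusted p of 0.165. The fry test for this list gave an adjusted p of 0.00466 towards higher values, and camera an adjusted p of 0.444, or an adjusted p of 0.594 with an estimated correlation. Its summed log2 difference was 0.21 (exact permutation p = 0.00794, adjusted p = 0.0337). Of the 14 lists with a set test, 3 passed camera with the preset correlation, all of the Dlk1-Dio3 locus, and 2 with an estimated one.

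Genotype lay along the main axis of variation, which held 43.4% of the variance, and the libraries also differed within genotypes. The locus members with their large differences were part of these values. The axes were not computed without them, so a separation of the other miRNAs by genotype is not shown. On the next axis, with 26.7% of the variance, control replicate 1 and Tsc1 mutant replicate 1 scored 12.9 and 10.4, and the others between -5.91 and 3.20. Control replicate 2 scored 10.6 on the third, and the others between -3.94 and 1.93. Without control replicate 1 and Tsc1 mutant replicate 1, 35 miRNAs rose and 11 fell, and 29 locus members rose. With control replicate 2 left out as well, 36 rose and 13 fell, and 30 locus members rose.

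**Figure D4:**
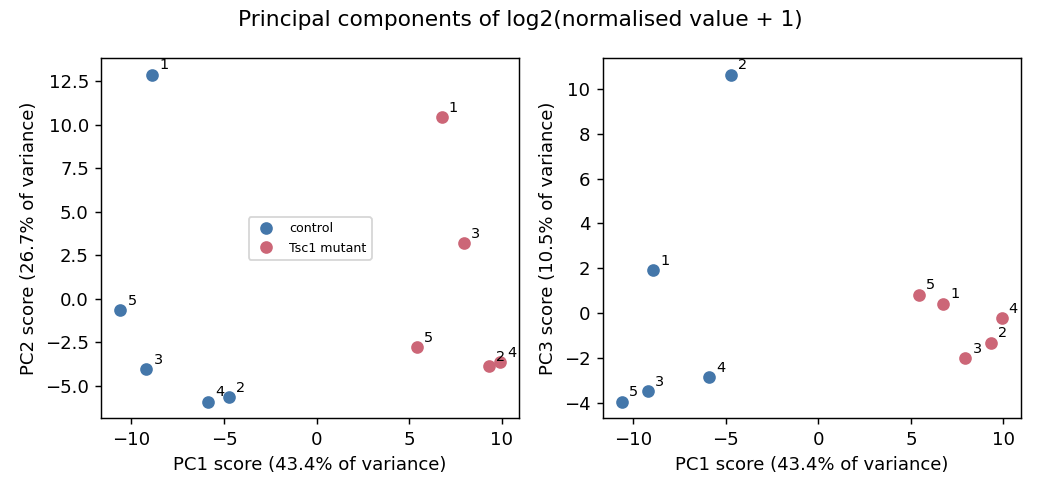
Scores of the 10 libraries on the leading principal components of log2(normalised value + 1), numbered by replicate, with controls in blue and Tsc1 mutants in red. The horizontal axis of both panels holds 43.4% of the variance, and the left vertical axis holds 26.7%.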

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

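Of the tests in this part, those on scaling, other tissues, hairpin GC content and sequencing depth were chosen after the data were seen, and so was the miR-122 test, for a pattern found in these libraries. In 15 of 144 groups of 5 values, 1 library stood apart from the other 4 by the gap between them, where chance gives about 7.2. The groups overlap, because list sums hold members that were also tested singly and locus members vary together. The 15 are therefore not separate events, and the excess over 7.2 was not tested.

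Tsc1 mutant replicate 5 had the lowest output of the Dlk1-Dio3 locus among mutants, with a sum of 15723 normalised reads against 24511 to 27083 in the other 4. The same library stood apart as the lowest mutant for miR-379 at 2043, miR-541 at 2662, miR-134 at 284 and miR-300 at 222 normalised reads. All these values lay above every control. Tsc1 mutant replicate 1 was the lowest mutant for let-7g at 289614 and miR-335-5p at 395 normalised reads. Control replicate 1 was the lowest control for miR-126-3p at 95159 and for the endothelial list at 113035, and the highest for miR-219-5p at 129. Control replicate 2 was the highest control for miR-200b at 20271, miR-1a at 5534 and miR-382 at 93.1, for the biliary epithelial list at 35789 and for the striated muscle list at 5638.

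The first pattern is the rise of the Dlk1-Dio3 miRNAs. Scaling between libraries would have moved the other miRNAs alike, but their median log2 fold change was -0.086 against 2.56. Because scaling itself sets the level of the other miRNAs, the rise is shown only relative to them. RNA of muscle or neural tissue in the mutants would have raised those markers, whose 5 members had a median of -0.67 with all libraries and of -0.49 (SD 0.68 over members) without control replicate 2, which lowers it, and miR-206 alone was above 0. With a slope on hairpin GC content removed from each library, the locus median stayed at 2.52. This covers only a linear effect of the hairpin's GC content, and that of the mature miRNAs was not tested. A change tied to the Tsc1 genotype is a hypothesis consistent with these values, and a change in the share of a cell type without a list here stays open.

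The counts were set against those of other splits of the libraries, which mix the genotypes. Of 100 splits of the 10 libraries, 1, the real one, called as many as 31 miRNAs in 1 direction, and the highest of the others called 1. The same held for the 6 that fell and for the 28 locus members, each reached by 1 split. The highest of the others was 1 in both. At 1 of 100 splits the counts are unlikely by chance, but a design of this size cannot exclude it. For the 6 that fell the comparison is weaker, because the many locus calls ease the Benjamini-Hochberg cutoff in the real split alone. For the camera p with the preset correlation, 2 of 100 splits were as small as the real 1.05e-48, and the other one, at 2.59e-50, exchanged control replicate 2 and Tsc1 mutant replicate 5. That split called 0 miRNAs, which shows how little the size of this p says.

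The next pattern is control replicate 2. Its biliary epithelial and striated muscle miRNAs exceeded the median of the other controls by a median of 2.99 on the log2 scale, and 7 of the 8 were at their highest there among the 10 libraries. Among them were miR-200b and miR-1a, and miR-375, in none of the lists, was at 990 against 38.7 normalised reads. Hairpin GC content was not related to the excess across miRNAs (Spearman -0.052, permutation p = 0.396). RNA of an epithelial and muscular tissue next to the liver is a candidate source, found and tested on the same library. Locus members were also higher there, by a median of 0.98 on the log2 scale, which lowers the difference between genotypes.

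The last pattern is that control replicate 1 and Tsc1 mutant replicate 1 deviated alike from their groups, with a correlation of 0.81 across miRNAs. The let-7 family was low in both, by a median of -1.43 and -1.15 on the log2 scale. Depth as the cause is argued against by their ranks of 3 and 4 of 5 by reads in their groups. Hairpin GC content was unrelated (Spearman 0.0045 across miRNAs, permutation p = 0.941). Without miR-122 and with the other values rescaled the correlation was 0.81. Leaving out 1 of 285 miRNAs and rescaling could hardly have changed it, so this decides nothing about miR-122. The design gives no group for these libraries, so no biological explanation was tested, and handling of the samples stays open.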

How the results depend on the processing

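The added voom, GC and combined left-out settings were chosen after the data were seen. Of the 37 called miRNAs, 30 passed in all 25 other settings that tested them, among them 27 of the 28 locus members, miR-802, miR-149 and miR-741. The exceptions were miR-433, miR-137, miR-29a, miR-582-3p, miR-320, miR-3962 and miR-1247, which lost the threshold 63 times in all. No called miRNA changed sign. The filter removed no miRNA, so leaving it out tests nothing. With a mean of at least 50, where 206 miRNAs were tested, 19 rose, 3 fell and 17 locus members rose. Array weights gave 40 that rose and 23 that fell, and the cause was not tested. Leaving out both replicates 1 gave 11 that fell, and leaving out control replicate 2 as well gave 13. Voom on whole reads called the same 31 and 6. The planned edgeR and DESeq2 fits were not run. Division gave whole reads, with fewer low values per library than the criterion used for a count model asks.

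With each library left out in turn, 28 to 34 miRNAs rose, 2 to 10 fell, 27 to 30 locus members rose, and the log2 difference of the locus sum was 2.52 to 2.80. The camera p was 4.36e-57 to 6.60e-33. The sum does not depend on pseudocount or model, so those settings were not counted for it.

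With the replicate number as a block, 35 rose and 10 fell. The log2 difference of the locus sum was 2.63 with p = 0.0625 by exact sign flips, the smallest that 5 pairs allow. Residual correlations of equally numbered libraries were 0.81, 0.16, -0.02, 0.46 and 0.05. Libraries 1 and 4 correlated best with their own number in both directions, a hint from the data and not the design, and the others did not. Since not every pair exceeded 0.1, the numbers were not taken as a pairing. Under the block let-7g (0.41, adjusted p = 0.0175) and miR-378 (0.44, adjusted p = 0.0365) also passed the threshold, as did miR-210 and 1 more locus member among those higher, and miR-1968, miR-296-3p, miR-455 and miR-92b among those lower.

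Signs changed 35 times in 9 miRNAs, none past the threshold, with adjusted p of at least 0.692. With scaling to the same total, miR-192 was at 0.040 and miR-126-3p at 0.022, with TMM miR-192 at 0.0070, and with ratios outside the locus miR-192 at 0.075 and miR-126-3p at 0.057. With array weights miR-148a was at -0.033, miR-30a at -0.0023 and miR-486 at -0.17. With the GC slope removed miR-192 was at 0.0037, miR-148a at -0.061 and miR-219-5p at 0.020. Without both replicates 1 miR-486 was at -0.13. With control replicate 2 out as well, miR-148a was at -0.037, miR-30a at -0.043, miR-486 at -0.12 and miR-200b at 0.0044, and miR-192 kept its sign at -0.178. With single libraries left out, miR-21 ranged from -0.30 to 0.12, miR-192 from -0.099 to 0.048, miR-148a from -0.0042 to 0.089, miR-30a from -0.0068 to 0.17, miR-335-5p from -0.22 to 0.0064, miR-486 from -0.17 to 0.30, miR-126-3p from -0.14 to 0.056, miR-219-5p from -0.45 to 0.059 and miR-200b, which kept its sign there, from -0.85 to -0.13. The cause was not tested. Depth limits miR-1247, miR-741 and miR-377, which had a few reads per library in 1 group.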

Other observations

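Both tests along the locus were chosen before their results were seen. The 2 parts of the Dlk1-Dio3 locus kept their proportion in summed reads. The log2 ratio of the part antisense to Rtl1 to the part from miR-379 to miR-410 was -0.46 ± 0.19 in controls and -0.47 ± 0.14 in mutants (SD, n = 5 each). The difference between genotypes was -0.0042 (exact permutation p = 0.984), which argues against the hypothesis that the sum of 1 part changed by another factor. The sums rest on abundant members, and single members were not compared by this test. Of the part antisense to Rtl1, miR-127 gave 1340 of 1584 normalised reads in controls and 8126 of 9627 in mutants. Whether the fold change depends on position cannot be told from these values. Across 29 hairpins, which are not independent replicates, the Spearman correlation of log2 fold change with hairpin start was -0.24 (permutation p = 0.202).

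At the Dio3 end of the domain, miR-1247 went the other way. Its hairpin lies on the minus strand, in an exon of Dio3os at 110278048 to 110278129 on chromosome 12 (GRCm38). The fixed list did not hold it, and hairpins of the listed members lie on the plus strand. It had 11.3 ± 5.61 normalised reads in controls and 2.42 ± 1.95 in mutants (SD, n = 5 each), a log2 fold change of -1.95 with a limma adjusted p of 0.0250. These values stand for a few reads, and miR-1247 was singled out after its value was seen. Its call may also lean on the cutoff eased by the locus calls. The call was lost in 7 of 24 other settings, among them the removal of the GC slope, with adjusted p from 0.0138 to 0.106.

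Within both genotypes, miR-34a and miR-744 varied strongly between libraries. In control replicate 1 and Tsc1 mutant replicate 1, miR-34a was at 537 and 503 normalised reads, against 26.7 to 207 in the others. Its log2 fold change between genotypes was 1.30 (limma adjusted p = 0.424), and it passed the threshold as higher in mutants with array weights, without control replicate 1, and in both settings without the 2 replicates 1. In the same libraries miR-744 was at 39.2 and 33.9 normalised reads, against 169 to 1050 in the others.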
